A study of Mus musculus with 3 samples.

How the data were processed

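Gene expression was measured on Affymetrix arrays in 3 samples of 1 group, ureteric tip cells from Hoxb7-GFP transgenic mouse embryos at 10.5 days post coitum. Per the labels, each sample was 1 ureteric bud and not a pool, dissociated with trypsin and sorted by fluorescence, and its RNA was amplified in 1 round and labelled with biotin. The replicate numbers 1 to 3 are those of the sample titles, and the arrays are called array 1, array 2 and array 3. Replicate numbers name the arrays and carry no order.

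The values deposited by the authors are 1 number per probe set and array on a log2 scale. The base was inferred from the values, whose powers of 2 fit the range of a common array scanner while powers of e do not, since no label states it. The summaries were made with Affymetrix Expression Console, per the submitters' processing notes, which give no version in the sources used here. The background correction, the normalization and the way probes were summarized are not given in the sources used here. The column medians were 5.47, 5.50 and 5.48 log2 on arrays 1, 2 and 3, so the columns arrived on nearly 1 common scale, and they were used as deposited. All 14486 probe sets (40.7% of 35557) that held 1 identical value on all 3 arrays, within a tolerance of 1e-06 log2, were kept. Their spread between buds is lost in the deposited values, so an SD of 0 there is a property of the table and not a measured agreement of the buds.

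Probe sets were named through the platform annotation: 21789 had 1 gene symbol, 1621 had several and 12147 had none listed. Of the probe sets with 1 symbol, 21698 had a gene ID in the RefSeq gene table (assembly GRCm38.p6), and 0 symbols differed. That table was used for names only, and no coordinates are given because the build behind the array is not given in the sources used here. Probe sets with several symbols or none were left out of gene counts. Probe sets of 1 gene were averaged on the log2 scale, which concerned 999 of the 19938 genes. The 39 gene lists held 904 members, of which 849 had a probe set with 1 symbol; the other 55 are not analysed here.

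The background level of an array was the 95th percentile of its 1035 olfactory receptor probe sets, genes taken as not used by this tissue. It was 5.40, 5.45 and 5.41 log2 on arrays 1, 2 and 3. For each gene, limma fitted the mean of the value minus its array's level, with a moderated one-sided test that this mean lies above 0 and Benjamini-Hochberg adjustment over all genes. A gene was above background at an adjusted p under 0.05. The prior had 1.71 degrees of freedom and an SD of 0.05 log2; both were estimated with the identical values included. For gene lists the share of members above background was set against all other named genes, without olfactory and vomeronasal receptors, by Fisher's exact test (two-sided), adjusted over 39 lists. The 3 bud lists (ureteric tip and RET pathway, nephric duct and bud, epithelial junction and polarity) were then pooled and set against each list of another cell type by the same test, adjusted over those lists, with shared genes left out. Genes are not independent replicates, so these tests describe the lists on these arrays.

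Agreement between arrays was described by correlations across genes, by the SD of each gene and by the share of genes whose highest and lowest array differed by over 1 log2. A list's shift on an array was the median, over members, of the value on that array minus the mean of the other arrays. Its two-sided p came from a permutation over genes, with 10000 random lists of the same size matched on mean signal in 20 bins. It was adjusted over 117 tests, and the smallest p these can give is 0.0002. Random lists were not matched on the share of identical genes, whose differences are 0 and pull a list's median to 0. A list with few identical members can therefore pass with a small shift. Each array is 1 bud, and the number of arrays limits the precision of every level. For genes identical on all 3 arrays the spread in the limma test comes from the 3 background levels and the prior, not from the buds, so their p-values measure no difference between samples. Levels of different probes were ranked to sort genes or probe sets by signal, and in alternatives that picked or filtered probe sets. Apart from the background level, no gene's signal was tested against another gene's.

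The groups, the gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, apart from 3 alternatives and the lists named as later ones in the closing section. Named genes were the first 12 measured members of the bud lists and of metanephric mesenchyme and the first 4 of every other list. They also include every Hox gene above background, all members above or not above background where a list had 5 or fewer of these, and every sex-linked gene. The last were the 10 genes above background with the largest difference between arrays. The alternatives were the 90th and 99th percentile, background families of vomeronasal receptors or of keratin-associated proteins and beta-defensins, and a rule without a model. Others were quantile normalization, median centring, the probe set with the highest mean, a filter that left out the lowest 25% of probe sets, leaving out each array in turn, and the mean in place of the median for shifts. Those chosen after seeing the data were an SD floor for identical values, leaving identical genes out of the detection test, and shifts over differing genes only. In 4 alternatives (vomeronasal receptors, without array 1, without array 3, and the SD floor) the limma prior had infinite degrees of freedom, so a pooled SD of 0.18 to 0.20 log2 stood for every gene. Calls gained there by genes with a wide spread, such as Xist and Hbb-y, are not evidence that these genes lie above background. Without array 2 the prior had 0.91 degrees of freedom and each gene's own spread was used. Calls lost or gained with an array left out thus reflect the change of fit as well as the array.

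The detection test was tested on simulated data for 19938 genes. With the spread of genes that differ between arrays, it called 14%, 46%, 66% and 88% of genes set 0.25, 0.5, 1 and 2 log2 above background, and 5 genes set at it. With the spread of all genes, identical ones included, the test called 70%, 62%, 78% and 72%. These shares do not rise steadily with the excess, and again 5 genes set at background were called. Both settings used 1 common background level for the 3 arrays, and this one gave identical genes almost no spread. In the data the 3 levels differed, so these shares do not give the power of the test that was run. The 5 genes called in each setting were set at the level itself. They do not show how many unused genes the test would call. Some olfactory receptors lie above the level by its definition as a percentile. The 90th percentile of keratin-associated proteins and beta-defensins, 6.68, 6.72 and 6.70 log2 on arrays 1, 2 and 3, also lay above it. That of vomeronasal receptors, 4.37, 4.50 and 4.45 log2, lay below it. The shift test, also on 19938 genes, called 0 of 117 shifts with none present and 5 of 5 lists shifted by 0.3 log2. These data were made by shuffling the spread between genes, which removes shared changes of related genes. It also evens out the share of identical genes between lists. The 0 of 117 therefore do not show how often such changes, or a low share of identical members, would alone lead to a call. The 0.3 log2 was added to every member, while identical members of the real lists stay at 0. The 5 of 5 may thus overstate the power. Computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.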

Results

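The ureteric bud is the epithelial outgrowth of the nephric duct that branches to form the collecting system of the kidney. Bud cells were taken from Hoxb7-GFP mice, in which Hoxb7 regulatory sequence drives green fluorescent protein in the nephric duct and bud. The embryos, of the CD-1 strain, were at 10.5 days post coitum (Theiler stage 18), and their sex is given as unknown. The 3 arrays form 1 group, each holding the sorted cells of 1 bud, so the design has no comparison between conditions. The comparisons open to it were which genes and gene groups lay above background, how bud genes stood against genes of other cell types, and how the buds differed from each other. Array medians were 5.47, 5.50 and 5.48 log2, and the background levels 5.40, 5.45 and 5.41 log2. The number of arrays limits the precision of every level, and values identical on all 3 arrays, which 10311 of 19938 genes (51.7%) had, carry no measured spread.

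Genes of the ureteric tip and the RET pathway were above background in 20 of 21 measured members, and also in 20 when adjusted over the list alone. Ret, the receptor tyrosine kinase for the growth factor GDNF, had a signal of 8.41 ± 0.26 log2 (SD, n = 3), and its co-receptor Gfra1 8.22 ± 0.37. The transcription factors Etv5 and Etv4, which act downstream of RET, had signals of 8.18 ± 0.18 and 6.22 ± 0.62 log2. Wnt11, a ligand secreted by bud tips, was at 6.05 log2, identical on all 3 arrays, and the chemokine receptor Cxcr4 at 8.98 ± 0.40. Sox9 had a signal of 7.45 ± 0.27 log2, Dusp6, a MAP kinase phosphatase, 7.30 ± 0.52, and Spry2, an inhibitor of receptor tyrosine kinase signalling, 6.55 ± 0.35. Its relative Spry4, at 5.34 log2 and identical on all 3 arrays, was the member not above background. The share of 95.2% compared with 56.1% of all other named genes (Fisher's exact test, two-sided, adjusted p = 0.00106). The calls of Etv4 and Wnt11 were lost at the 99th percentile (limma, adjusted p of 0.677 and 1) and with keratin-associated proteins and beta-defensins as background, and that of Etv4 also without array 2 (limma, adjusted p = 0.217). Dusp6 and Spry2 were among the others lost with the latter background. With the lowest 25% of probe sets left out the list no longer differed from other genes (adjusted p = 0.068).

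Transcription factors and markers of the nephric duct and bud were above background in 24 of 25 measured members, and in 24 adjusted over the list alone. Pax2 had a signal of 8.22 ± 0.33 log2 (SD, n = 3), Pax8 6.31 ± 0.29, Gata3 9.13 ± 0.13 and Lhx1 7.17 ± 0.52, all of them transcription factors needed for the duct or bud. Calb1, a calcium-binding protein used as a marker of this epithelium, was at 11.47 ± 0.07 log2. Hoxb7, whose regulatory sequence labels the sorted cells, was at 7.01 ± 0.15 log2, Emx2 at 7.51 ± 0.06, Wnt9b at 6.16 ± 0.08 and Fgfr2 at 8.35 ± 0.20. Elf5, identical on all 3 arrays at 5.00 log2, was not above background. The list differed from all other named genes (96.0% against 56.1%, Fisher's exact test, adjusted p = 0.000132). Pax8 and Wnt9b lost their calls at the 99th percentile (limma, adjusted p of 0.115 and 0.0903) and with keratin-associated proteins and beta-defensins as background, and Pax8 also without array 2 (limma, adjusted p = 0.0506). Lhx1 and Hoxb7 lost theirs with the latter background (limma, adjusted p of 0.414 and 0.289).

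Genes of epithelial adhesion, keratins and polarity were above background in 29 of 30 measured members, and in 29 adjusted over the list alone. The cell adhesion genes Cdh1 and Epcam had signals of 7.62 ± 0.16 log2 (SD, n = 3) and 9.27, the second identical on all 3 arrays. The keratins Krt8 and Krt18 were at 10.11 ± 0.58 and 8.79 ± 0.01 log2, while Krt19, at 5.46 ± 0.07, was not above background. The tight junction genes Cldn7 and Cldn6 were at 9.51 ± 0.30 and 7.94 ± 0.04 log2, the splicing regulator Esrp1 at 9.39 ± 0.41 and the transcription factor Grhl2 at 7.87, identical on all 3 arrays. The share of 96.7% exceeded that of other named genes (Fisher's exact test, adjusted p = 8.61e-06), but not with identical genes left out (adjusted p = 0.0512). Over all genes, limma called 10567 of 19938 (53%) above background, 4449 of them identical on all 3 arrays. The count was 7034 with the 99th percentile of olfactory receptors and 4210 with keratin-associated proteins and beta-defensins as background, which left 11, 15 and 16 members called in the 3 bud lists.

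**Figure D1:**
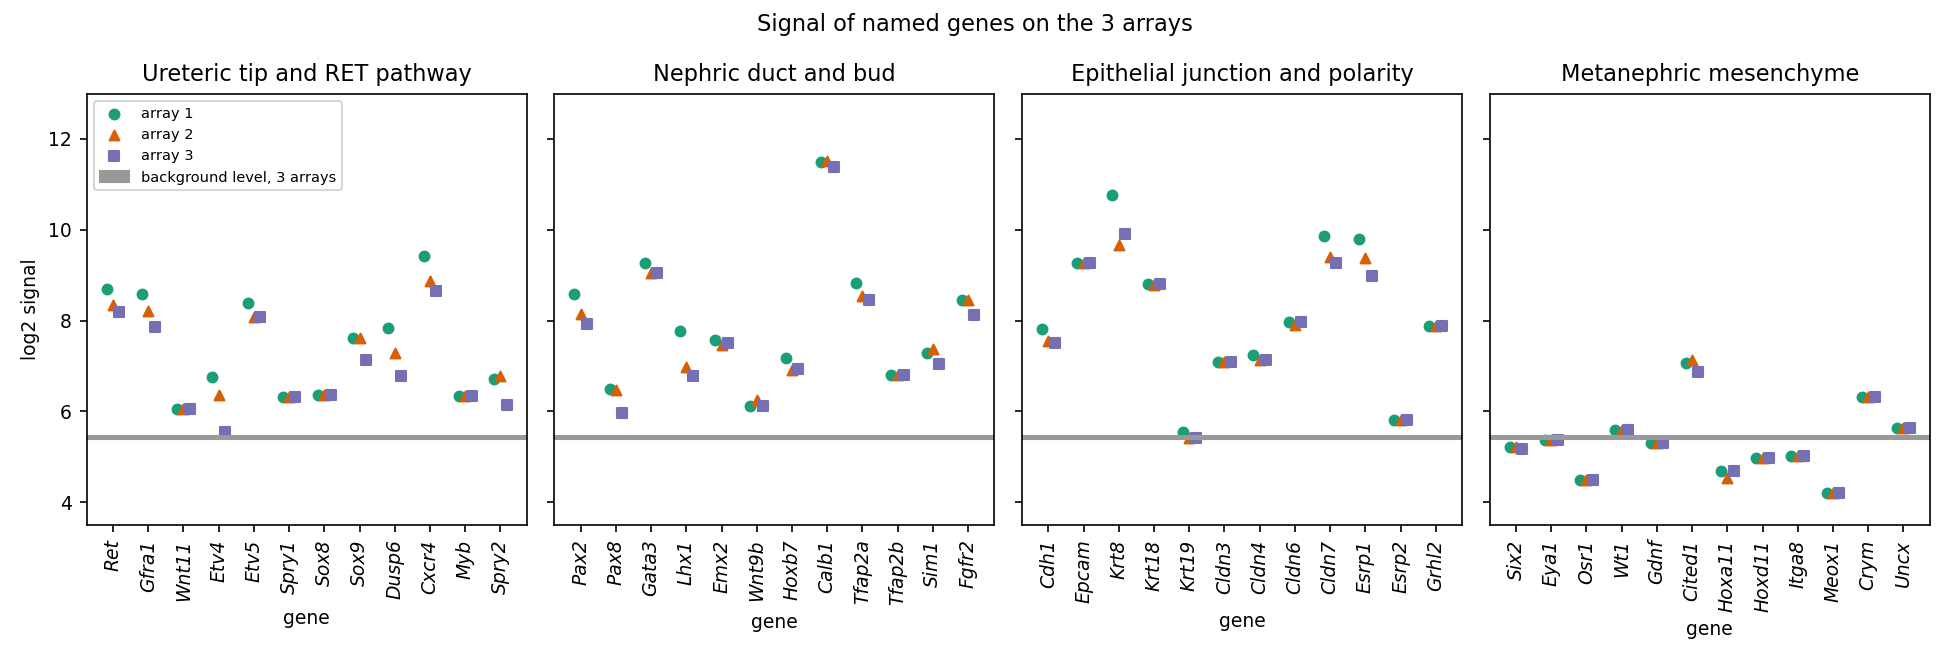
Signal (log2, vertical axis) of the first 12 measured members of 4 gene lists on each of the 3 arrays (points), with the background levels of the 3 arrays as a grey band. Members of the 3 bud lists sit above the band apart from Krt19 at 5.46 log2, and Etv4 lies near it on array 3 at 5.54 log2, while members of the metanephric mesenchyme list lie on both sides.

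Genes of the metanephric mesenchyme, the tissue that the bud grows into, were above background in 9 of 19 measured members, and in 9 adjusted over the list alone. The nephron progenitor gene Six2 was at 5.20 ± 0.02 log2 (SD, n = 3), and Gdnf, Eya1 and Osr1 were at 5.32, 5.36 and 4.50 log2, each identical on all 3 arrays and none above background. Cited1 was above it at 7.02 ± 0.14 log2, as were Robo2 at 8.51 ± 0.18 and Capn6 at 8.35 ± 0.18, which are named here after their values were seen. Wt1 (5.60 log2) and Uncx (5.64 log2), both identical on all 3 arrays, were above background, though neither with an SD floor for identical values. The pooled bud lists, with 73 of 76 members above background (96.1%), exceeded the mesenchyme list by 48.7 percentage points (Fisher's exact test, adjusted p = 2.57e-06). The mesenchyme count was 5 with the 99th percentile and 2 with keratin-associated proteins and beta-defensins as background, where Cited1 lost its call.

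Endothelial genes were above background in 15 of 18 measured members, and in 16 adjusted over the list alone. The vascular adhesion genes Pecam1 and Cdh5 had signals of 6.27 ± 0.38 and 7.39 ± 1.30 log2 (SD, n = 3), the angiopoietin receptor Tek 6.57 ± 0.84 and the sialomucin Emcn 8.22 ± 1.42. The VEGF receptor Kdr (6.30 ± 0.75 log2), Esam (5.78 ± 0.37) and Sox17 (5.87 ± 0.49) did not pass the test. The share of 83.3% lay 12.7 percentage points below that of the bud lists, which did not pass the threshold (Fisher's exact test, adjusted p = 0.082). The difference passed it at the 99th percentile (60.7 points, 4 members called), with keratin-associated proteins and beta-defensins as background (55.3 points, 0 called), with quantile normalization (18.3 points), with identical genes left out (16.7 points) and without array 3 (16.96 points). Against all other named genes the endothelial list did not pass in the main analysis (Fisher's exact test, adjusted p = 0.0863) and was higher in 6 alternatives, among them the 90th percentile (32.7 points, adjusted p = 0.00725) and without array 2 (38.6 points, adjusted p = 0.00299). Over all alternatives the adjusted p of the difference from the bud lists ran from 2.16e-06 to 1, and the difference was −2.34 points without array 2. It was also below 0 at the 90th percentile and with vomeronasal receptors as background, where endothelial genes were called at least as often as bud genes. The fit without array 2 used each gene's own spread and those without array 1 or array 3 a pooled SD, so their differences are not like for like.

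The bud lists exceeded every list of another cell type other than endothelium, by 48.7 to 77.3 percentage points (Fisher's exact test, adjusted p at most 1.08e-05). Leukocyte and macrophage genes were above background in 3 of 16 members (Cx3cr1, Cd68 and C1qc), fewer than other named genes (18.8% against 56.1%, Fisher's exact test, adjusted p = 0.017), and Csf1r at 4.56 log2, Ptprc at 4.48 and Adgre1 at 4.10, each identical on all 3 arrays, were not above it. Erythroid genes were above in 4 of 11, namely the embryonic globin Hba-x at 7.08 ± 1.08 log2 (SD, n = 3), Alas2, Slc4a1 and Tal1, while the embryonic globins Hbb-y, at 7.62 ± 1.86, and Hbb-bh1, at 5.35 ± 0.95, did not pass. Stroma and other mesenchyme gave 7 of 22, without Foxd1 (3.42 log2), Tcf21 (4.65), Pdgfra (4.94) or Pdgfrb (4.48), each identical on all 3 arrays. Neural crest and neuron genes gave 5 of 14 (Sox10, Isl1, Erbb3, Hand2 and Th), germ cell genes 3 of 12 (Nanos3, Ifitm3 and Kit), and somite and muscle genes 4 of 12 (Myod1, Pax7, Actc1 and Tcf15). Gonadal ridge and coelomic genes gave 4 of 12, 3 adjusted over the list alone (Gata4, Wt1, Emx2 and Lhx2, of which Emx2 is also a bud gene), and gut and cloacal endoderm 5 of 14 (Shh, Hnf4a, Cdx1, Ihh and Apoa1). Genes of the later kidney gave 7 of 15 for podocytes and nephron tubules and 8 of 23 for differentiated collecting duct and urothelium, with the water channel gene Aqp2 at 6.26 log2, identical on all 3 arrays. At the 99th percentile the counts fell to 0 of 11 for erythroid genes, 4 for stroma, 2 each for leukocytes, neural crest, germ cells and gut, 1 each for somite and muscle, gonadal ridge and the mature nephron, and 3 for the collecting duct. The erythroid, nephron and collecting duct lists were then lower than other genes (Fisher's exact test, adjusted p of 0.036, 0.0489 and 0.0489). With keratin-associated proteins and beta-defensins as background 2 germ cell genes and 1 gonadal gene were left in these lists. Stroma and germ cell genes were lower than other genes at the 90th percentile (Fisher's exact test, adjusted p of 0.0323 and 0.0143) though not in the main analysis (adjusted p of 0.0863 and 0.104). The leukocyte call was lost in 4 of the alternatives, among them the 99th percentile (adjusted p = 0.0874), and the mature nephron difference fell to 31.3 points with identical genes left out (adjusted p = 0.113).

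**Figure D2:**
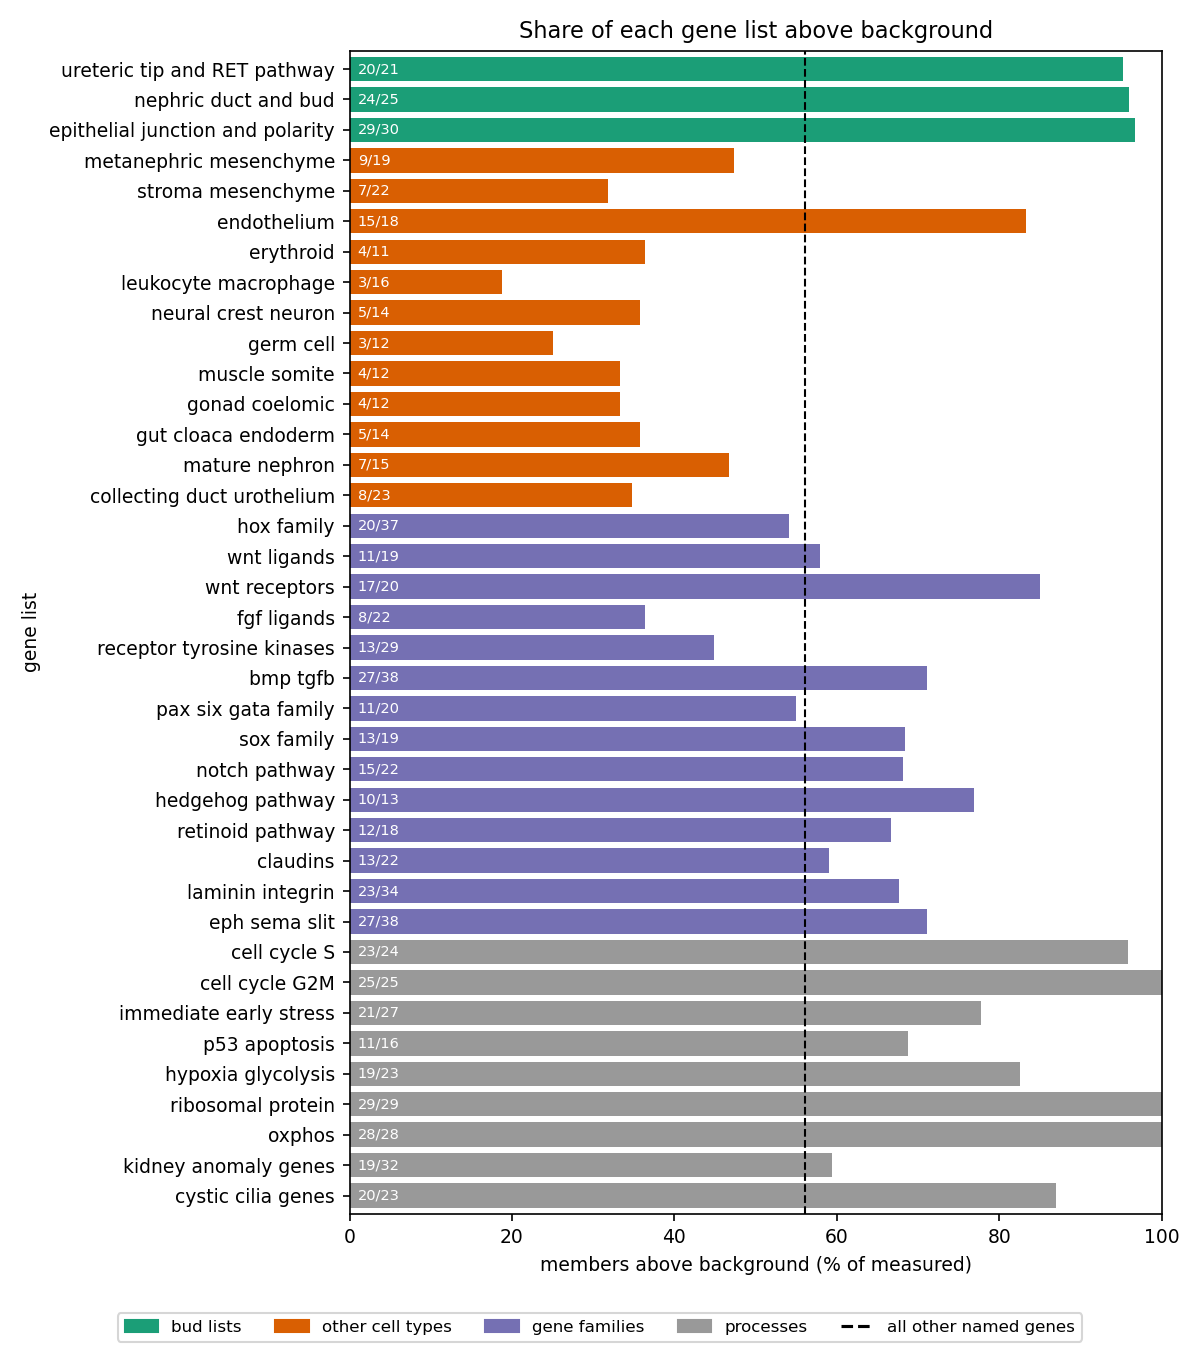
Share of measured members above background (percent, horizontal axis) for 38 of the gene lists, without the sex-linked genes, with the count above and the count measured at each bar and all other named genes as a dashed line at 56.1%. The 3 bud lists reach 95.2% to 96.7%, and leukocyte and macrophage genes 18.8%.

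Among gene families, 20 of 37 measured Hox genes, the homeobox genes that mark position along the body axis, were above background (54.1%, Fisher's exact test against other genes, adjusted p = 0.941). The HoxB cluster had 8 of 9 members above background, with Hoxb4 at 7.95 log2, identical on all 3 arrays, Hoxb5 at 8.39 ± 0.03 (SD, n = 3) and Hoxb6 at 8.18 ± 0.07. HoxA had 6 of 10, HoxD 5 of 9, with Hoxd8 at 8.22 ± 0.36 log2, and HoxC 1 of 9, the one being Hoxc4 at 5.98 ± 0.09. Hoxa11 (4.64 ± 0.09 log2) and Hoxd11 (4.98 log2, identical on all 3 arrays) were not above background. At the 99th percentile 15 Hox genes were above background, without Hoxa2, Hoxa6, Hoxa9, Hoxb1 and Hoxc4, and with keratin-associated proteins and beta-defensins as background 8 were, none of them in HoxC. The call of Hoxa6, at 5.49 log2, was also lost with an SD floor, with quantile normalization and without array 1 or array 3.

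**Figure D3:**
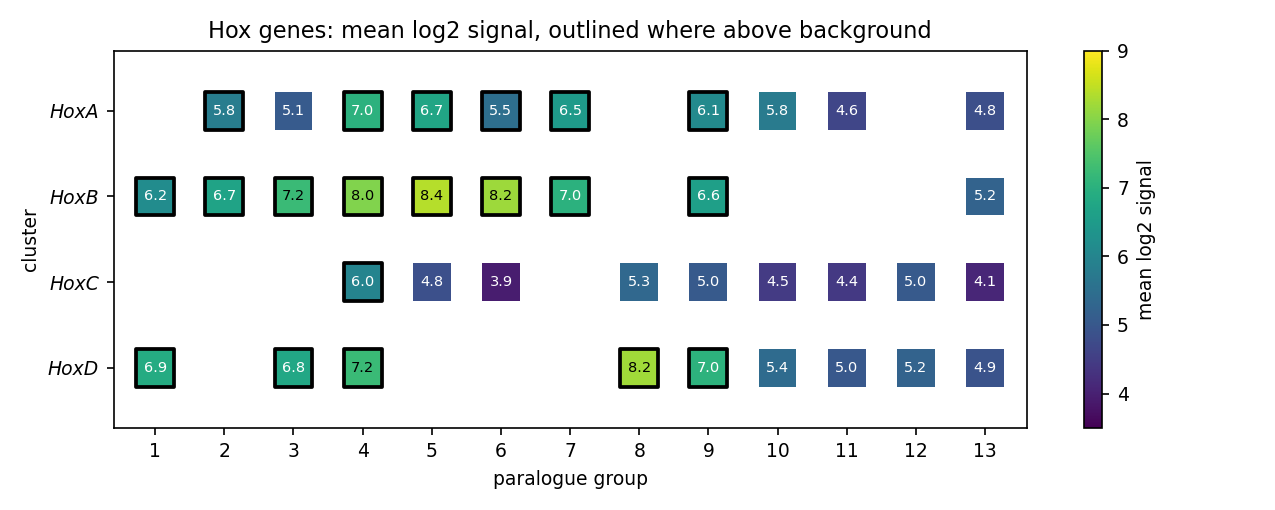
Mean log2 signal over the 3 arrays (colour and number) of each measured Hox gene by cluster (rows) and paralogue group (columns), with genes above background outlined. Outlined genes fill 8 of 9 positions in HoxB and 1 of 9 in HoxC.

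Wnt receptors and co-receptors were above background in 17 of 20 members, more often than other genes (85.0%, Fisher's exact test, adjusted p = 0.04), with Fzd3 at 7.90 ± 0.09 log2 (SD, n = 3) and Fzd4 at 7.76 ± 0.04, and without Fzd8, Ror1 and Lgr6. None of the other families described here passed the threshold in the main analysis (Fisher's exact test, adjusted p of 0.156 or more). Wnt ligands were above background in 11 of 19 members, among them Wnt7b at 5.78 log2, identical on all 3 arrays, and FGF ligands in 8 of 22, among them Fgf3 at 5.68 log2, identical on all 3 arrays. Receptor tyrosine kinases gave 13 of 29, BMP and TGF-beta genes 27 of 38, with Bmp4 at 6.57 and Bmp7 at 7.31 log2, both identical on all 3 arrays, and the Notch pathway 15 of 22. The Hedgehog pathway gave 10 of 13, with the receptor Ptch1 at 7.71 ± 0.39 log2, and the retinoid pathway 12 of 18, with the retinoic acid synthesis enzymes Aldh1a3 at 9.19 ± 0.22 and Aldh1a1 at 7.80 ± 0.17 above background and Aldh1a2 at 5.40 ± 0.07 not. Pax, Gata and sine oculis factors gave 11 of 20, Sox factors 13 of 19, claudins 13 of 22, and laminins, collagen IV and integrins 23 of 34. Eph, ephrin, semaphorin, Slit and Robo genes gave 27 of 38, or 28 adjusted over the list alone. The Wnt receptor call was lost at the 99th percentile (adjusted p = 0.126), without array 2 (adjusted p = 0.105) and in 3 other alternatives, and the Wnt ligands were less often above background than other genes at the 99th percentile (−27.0 points, adjusted p = 0.0489). FGF ligands were less often above background than other genes at the 90th and 99th percentile (−26.4 and −33.0 points, Fisher's exact test, adjusted p of 0.0323 and 0.00306) and with keratin-associated proteins and beta-defensins as background (−22.5 points, adjusted p = 0.028). The Eph and semaphorin list was more often above background at the 90th percentile (19.6 points, Fisher's exact test, adjusted p = 0.0287), with vomeronasal receptors as background (18.1 points, adjusted p = 0.0418) and by the rule without a model (21.8 points, adjusted p = 0.0277), as were the Hedgehog pathway with vomeronasal receptors (31.3 points, adjusted p = 0.0418) and the laminin list without array 2 (23.6 points, adjusted p = 0.0189).

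Genes of cell division, translation and respiration were above background in nearly all measured members. S phase genes were above in 23 of 24, with the replication helicase genes Mcm2 at 7.83 ± 0.08 log2 (SD, n = 3) and Mcm4 at 8.68, identical on all 3 arrays, and without E2f1 at 5.44 log2. Mitosis genes were above in 25 of 25, with Cdk1 at 10.01 ± 0.08 log2 and Top2a at 7.78 ± 0.01, ribosomal protein genes in 29 of 29 and respiratory chain genes in 28 of 28. Each of these lists exceeded other named genes (Fisher's exact test, adjusted p of 0.0002, 7.33e-06, 3.02e-06 and 3.02e-06). Glycolysis and hypoxia-inducible genes gave 19 of 23, with the glucose transporter gene Slc2a1 at 8.71 ± 0.33 log2 and without Pfkp, Egln3, Car9 and Adm (Fisher's exact test, adjusted p = 0.04). Polycystic disease and ciliary genes gave 20 of 23 (Fisher's exact test, adjusted p = 0.0125). Immediate early and dissociation stress genes gave 21 of 27 (adjusted p = 0.0863, but 0.0338 at the 90th percentile and 0.0373 with the probe set of the highest mean), with Jun at 8.16 ± 0.20 log2 and Fos at 5.49 log2, identical on all 3 arrays. The p53 and apoptosis genes gave 11 of 16, or 12 adjusted over the list alone, and genes of congenital kidney and urinary tract anomalies 19 of 32. For every list without its own statement, the count adjusted over the list alone was the same as over all genes. The ciliary call was lost without array 1 and without array 3 (adjusted p of 0.0882 and 0.0963) and the glycolysis call at the 90th percentile (adjusted p = 0.292), among other alternatives.

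Of the sex-linked genes, 4 of 7 were above background. The Y-linked genes Eif2s3y, Uty and Sry had signals of 7.14 ± 0.34, 6.38 ± 0.17 and 6.43 ± 0.36 log2 (SD, n = 3), and Kdm5d 6.17 log2, identical on all 3 arrays, while Usp9y (3.18 ± 0.04) and Zfy1 (2.92, identical on all 3 arrays) were not above it. Xist, the RNA that coats the inactive X chromosome, was at 7.14, 4.35 and 9.04 log2 on arrays 1, 2 and 3, and its mean did not pass the limma test (adjusted p = 0.217). The calls that Xist gained in some alternatives rest on fits that did not use each gene's own spread.

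The 10 genes above background with the largest differences were Tmem255a, Aplnr, Emcn, Zdhhc15, Eif3d, Ldb2, Mrps26, Snora23, Gm24463 and Cdh5. Tmem255a was at 8.64, 5.87 and 9.29 log2 on arrays 1, 2 and 3, the apelin receptor gene Aplnr at 9.32, 7.21 and 10.23, and Emcn at 8.37, 6.73 and 9.55. Eif3d, a translation initiation factor gene, was at 11.74, 9.29 and 9.28 log2, and the small nucleolar RNA gene Snora23 at 9.15, 9.26 and 6.92. Across the 19938 named genes, Pearson's r between pairs of arrays was 0.991, 0.989 and 0.990 and Spearman's rho 0.991, 0.989 and 0.989. Genes are not independent replicates, and no p is given. The 10311 genes identical on all 3 arrays are included and carry no measured agreement of the buds. Correlations over differing genes alone were not computed. Among genes not identical on all 3 arrays the median SD was 0.10 log2. The highest and lowest array differed by over 1 log2 in 473 genes (2.37%), of which 291 were above background. Over all 35557 probe sets the share that differed by over 1 log2 was 10.8%.

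Of 117 shifts of a list on 1 array, 7 passed the threshold, and they lay in 3 lists. A gene's differences on the 3 arrays cancel by definition, so the shifts of 1 list are not separate results. A list higher on 1 array alone is thereby lower on the others. Endothelial genes were lower on array 2 than on the mean of the other arrays, with a median shift of −0.54 log2, 16 of 18 members lower and 0 higher, and higher on array 3, with a shift of 0.38 log2 and 16 members higher (random-list adjusted p = 0.0078 for both). Cdh5 was at 8.22, 5.89 and 8.07 log2 on arrays 1, 2 and 3, Tek at 6.69, 5.67 and 7.34, and Kdr at 6.32, 5.55 and 7.04. On array 2 the median of the endothelial list was 5.79 log2, not far above the background level of 5.45. The size of the endothelial shift is therefore uncertain. The endothelial shift on array 1 was 0.074 log2, with 11 members higher and 5 lower (adjusted p = 0.0351). Glycolysis genes were higher on array 1 by 0.23 log2, with 17 of 23 members higher and 1 lower (adjusted p = 0.0078), and lower on arrays 2 and 3, with shifts of −0.12 and −0.10 log2 and 15 members lower on each (adjusted p of 0.0281 and 0.0234). Slc2a1 was at 9.04, 8.39 and 8.70 log2 and Hk2, a hexokinase gene, at 6.35, 6.12 and 6.12. Respiratory chain genes were higher on array 3 by 0.050 log2 (adjusted p = 0.0435). Members identical on all 3 arrays numbered 2 of 18 for endothelium, 5 of 23 for glycolysis and 2 of 28 for the respiratory chain. These shares are lower than the 51.7% over all genes. The random lists were not matched on this share, so the calls of the smaller shifts may partly reflect it. The ureteric tip and RET list had a shift of 0.12 log2 on array 1, with 13 of 21 members higher and 1 lower, that did not pass (adjusted p = 0.0728), with Ret at 8.69, 8.35 and 8.18 log2 and Etv4 at 6.76, 6.37 and 5.54. On array 1 the nephric duct list had 16 of 25 members higher and 1 lower, the epithelial junction list 17 of 30 higher and 1 lower, and mitosis genes 19 of 25 higher and 0 lower, with shifts of 0.071, 0.047 and 0.051 log2 that did not pass (random-list adjusted p of 0.169, 0.304 and 1). On array 3 the tip list had a shift of −0.077 log2 and the nephric duct list one of −0.066, with 12 and 15 members lower and 2 higher in each, and neither passed (random-list adjusted p of 0.131 and 0.0728). Over members above background only, the tip list passed on arrays 1 and 3 and the nephric duct list on array 3 (random-list adjusted p of 0.0263, 0.0286 and 0.0263). Immediate early and dissociation stress genes had 13 of 27 members lower and 3 higher on array 2 and 13 higher and 3 lower on array 3, with median shifts of 0 (random-list adjusted p = 1), and passed on array 3 over members above background and over differing genes (random-list adjusted p of 0.0362 and 0.0234). The embryonic globin Hbb-y was at 8.86, 5.48 and 8.52 log2 and Hba-x at 7.98, 5.87 and 7.39, but the erythroid list had a median shift of 0 on array 2, where most of its members are identical. With the mean in place of the median the erythroid shift on array 2 was −0.59 log2 (random-list adjusted p = 0.00585). This mean rests on the embryonic globins Hbb-y, Hba-x and Hbb-bh1. On array 2 Hbb-y lay near the background level of 5.45 log2 and Hbb-bh1, at 4.42, below it, so the size of the shift is uncertain. Endothelium on arrays 2 and 3 and glycolysis on array 1 passed under each alternative run, and the other 4 shifts each lost the call under at least 1.

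**Figure D4:**
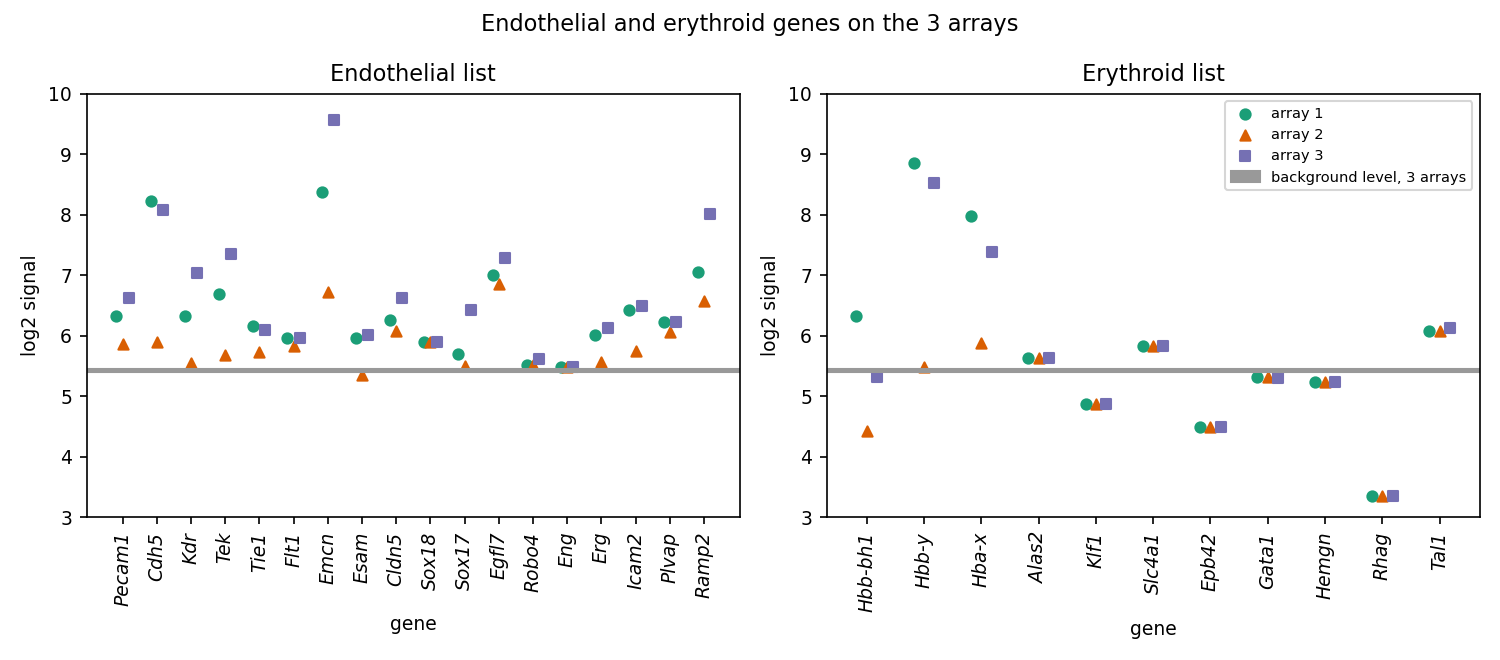
Signal (log2, vertical axis) of each measured endothelial and erythroid list member on the 3 arrays (points), with the background levels as a grey band. Array 2 is the lowest for Cdh5 at 5.89 log2, Emcn at 6.73 and Hbb-y at 5.48, while erythroid genes such as Alas2 coincide on all arrays.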

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

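The comparison given here was chosen only after the result was seen. Probe sets with no gene listed take no part in the comparisons of named genes, yet 4216 of them lay above the background level on all 3 arrays. That is 34.7% of the 12147 probe sets with no gene listed, against 54.96% of probe sets with 1 symbol. What they measure is unnamed here, and no explanation was tested. Groups of 3 arrays were not searched for single arrays far from the others, and there is 1 group, so no difference of effects between groups exists.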

How the results depend on the processing

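The alternatives that left identical genes out, raised their SD or used differing genes only for shifts were chosen after seeing the data. No paired analysis was possible because there is 1 group. Of 14 alternatives for detection, 3 moved the number of genes above background by over 1.5 times, to 7034 (99th percentile), 4210 (keratin-associated proteins and beta-defensins) and 6078 of the 9627 genes left when identical genes were left out, where fewer genes were tested. The others gave 9666 to 12987 genes, and median centring cannot change a call because each array's background is subtracted. At the 99th percentile, 5 mesenchyme and 4 endothelial members were above background, 5 lists were lower than other genes and the bud lists exceeded endothelium by 60.7 points. With keratin-associated proteins and beta-defensins, the members above background were 11 for the tip, 15 for the duct and bud, 16 for epithelial junctions, 2 for mesenchyme and 0 for endothelium, 4 lists were lower, and the difference from endothelium was 55.3 points. Of the named genes that lost their call, 38 of 53 at the 99th percentile and 84 of 96 with keratin-associated proteins and beta-defensins had a mean below the new level. Wnt ligands reversed from 57.9% against 56.1% of other genes to differences of −27.0 points at the 99th percentile and −22.5 points with keratin-associated proteins and beta-defensins. The levels of the latter, 6.82, 6.91 and 6.87 log2 on arrays 1, 2 and 3, lay above the mean of every measured Wnt ligand. This includes Wnt5b at 6.66 log2, so the reversal there follows from the higher level. No cause beyond this was tested.

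The number of lists lower than other genes was 4 at the 90th percentile, 2 with vomeronasal receptors, and 1 to 2 with an array left out. With the lowest 25% of probe sets left out it was 0, with 6 lists higher, since fewer genes at low signal remained in the comparison. With identical genes left out it was also 0, with 6 higher, 17 of 18 epithelial and 5 of 7 mesenchyme members above background, an endothelial difference of 16.7 points and a mature nephron difference of 31.3 points that no longer passed (adjusted p = 0.113); the gonadal list, left without unshared genes, gave no value. The endothelial difference was 18.3 points with quantile normalization. It ran from −2.34 to 16.96 points with an array left out, in fits that did not treat the spread of genes alike. For bud lists against other cell types, 161 values over the alternatives kept their side of the threshold, 5 gained the call (endothelium) and 1 lost it. For lists against other genes, 494 values kept it, 26 gained the call in the same direction, 2 (Wnt ligands) gained it with the sign reversed and 24 lost it, and for named genes 2951 kept it, 89 gained the call and 212 lost it.

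The median correlation was 0.984 over genes above background and 0.965 over all probe sets, and 0.989 to 0.991 with an array left out. Each of these sets includes identical values, which carry no measured agreement of the buds. The share differing by over 1 log2 was 2.75% over genes above background, 10.8% over all probe sets and 1.12% to 1.32% with an array left out, where 2 arrays have a smaller range than 3. Called shifts numbered 12 over members above background and 11 over differing genes. With the mean in place of the median the call was lost for endothelium on array 1 (0.12 log2), glycolysis on arrays 2 and 3 (−0.16 and −0.16 log2) and respiratory chain genes on array 3 (0.027 log2). Over differing genes it was lost for endothelium on array 1 (0.084 log2), glycolysis on array 2 (−0.20 log2) and respiratory chain genes on array 3 (0.072 log2), the last also with quantile normalization (0.052 log2). For these shifts the cause was not tested. Signal near background limits the calls: 16 named genes, among them Hoxa6, Wt1 and Shh, lost theirs with an SD floor for identical values.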

Other observations

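Of the tests given here, those on a second endothelial list, a second erythroid list and X-linked genes that escape inactivation were set down before their results were seen, and all the other tests were chosen after. Hox genes above background were unevenly spread over paralogue groups. Of the 12 measured genes of groups 10 to 13, 0 were above background, against 20 of 25 in groups 1 to 9 (Fisher's exact test, two-sided, p = 3.34e-06), with Hoxa11 at 4.64 ± 0.09 log2 (SD, n = 3) and Hoxd11 at 4.98 log2, identical on all 3 arrays. Hoxa10, named here after its values were seen, was at 5.78 ± 0.29 log2 and did not pass. Within groups 4 to 9, HoxC had 1 of 5 genes above background and the other clusters 13 of 13 (Fisher's exact test, two-sided, p = 0.00163). Under 4 other background levels the first difference had a Fisher's exact p from 0.000366 to 0.0357, and the second had an exact p of 0.101 with keratin-associated proteins and beta-defensins and 0.00245 to 0.0123 otherwise. Both groupings were taken from the same calls, so these p-values describe the pattern and are no independent evidence for it.

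Genes of small nucleolar, Cajal body and micro RNAs, chosen as a class after the values were seen, differed between arrays more often than others. Of 345 such genes, 55 (15.9%) differed by over 1 log2 between highest and lowest array, against 418 of 19593 other genes (2.13%, Fisher's exact test, two-sided, p = 1.27e-29). The class was chosen from the same values, so this p describes the pattern and is no independent evidence for it. The genes compared were not matched on signal. Snora23 was at 9.15, 9.26 and 6.92 log2 on arrays 1, 2 and 3, and no cause was tested.

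Most endothelial genes that differed, and the embryonic globin Hbb-y, were lowest on array 2, with Emcn at 8.37, 6.73 and 9.55 log2, Cdh5 at 8.22, 5.89 and 8.07 and Hbb-y at 8.86, 5.48 and 8.52 on arrays 1, 2 and 3. Of the 16 endothelial members that differed between arrays, 93.8% were lowest there, and a second endothelial list of 34 genes had 15 of 22 differing members lowest there. Its median shift was −0.055 log2 on array 2, with 21 members lower and 1 higher, and 0.034 on array 3, with 20 higher and 2 lower (permutation over genes by random lists, p = 0.0002 for both, the smallest these can give), so array 3 stands out as array 2 does. Identical values pull these medians towards 0, and the mean shifts were −0.295 and 0.337 log2 (permutation p = 0.0002 for both). A weaker or compressed signal across array 2 as the whole cause is argued against by the deposited values. The mean difference on array 2 was 0.024 log2 over the genes of lowest signal and −0.048 over those of highest signal. The median endothelial shift there was −0.535 log2, a size left uncertain by signals near background on array 2. Quantile normalization adds little to this, since the arrays already matched closely. It moved the difference on array 2 by over 0.01 log2 in 89.0% of genes, with an SD of the move of 0.037. A step of that size could not have removed the endothelial shift, which was −0.565 log2 afterwards (permutation p = 0.0002). Signal lost before the deposited summaries were made was not tested. For red blood cells the second list, of 22 genes, had a mean shift of −0.049 log2 (permutation p = 0.272). This met the bound for failure set in advance, and it was left open only after the result was seen, because 12 of its genes were above background and 10 differed at all, so that bound could not separate a small share of such cells from none. Immediate early and dissociation stress genes leaned the same way, with 13 of 27 lower and 3 higher on array 2 and 13 higher and 3 lower on array 3. The median shift was 0 on both (permutation p = 1), which the 11 members identical on all 3 arrays bring about. The mean shifts were −0.193 and 0.17 log2. Over members above background and over differing genes the list passed on array 3, as given above. Whether handling of the buds differed was not tested. A candidate explanation is that the sorted buds carried differing numbers of endothelial cells, which a sort on GFP should largely leave out. Of the 18 listed genes, 4 (Cldn5, Sox17, Sox18 and Kdr) also stand in family lists. Apart from endothelial and red blood cells no biological explanation was tested, since the labels give the buds no group.

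Identical values on all 3 arrays fell in 14486 of 35557 probe sets. Among the 21789 probe sets with 1 symbol they made up 18.8% to 66.8% of 10 bins by signal. A floor or rounding of low values is argued against, since 43.8% of identical genes lay above the background level, and so is 1 library deposited repeatedly, since 32.8% of genes differed by over 0.1 log2. Simulated probe sets summarized by median polish over 3 arrays, matched to the share identical on all 3, gave the share with exactly 2 equal arrays to within a median of 1.29 percentage points, whereas a summary by means gave no equal values. Median polish may therefore be the source, as a hypothesis, and no biological explanation was tested.

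Xist was at 7.14 and 9.04 log2 on arrays 1 and 3 and below the background level of 5.45 log2 on array 2, so the size of the difference is not given. Of the 4 Y-linked genes above background, Eif2s3y, Uty and Sry were higher on array 2, where Xist was lowest. Kdm5d was identical on all 3 arrays. The mean difference of the 4 genes was 0.354 log2 (SD 0.272), in the direction that embryos of different sex would give. This comparison was chosen after the values were seen, has no random-list p and leaves out Usp9y and Zfy1. The 4 genes were above background on all 3 arrays. X-linked genes that escape inactivation differed on array 2 by 0.013 log2 (SD 0.098, 7 genes, permutation p = 0.476). This too met the bound for failure set in advance, and it was left open after the result was seen because the difference is less than the spread of the genes. The sex of the embryos therefore stays open, and a mix of cells or probes that bind related X-linked transcripts was not tested.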
